A study of Mus musculus with 2 samples.

How the data were processed

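Two-colour arrays of cultured embryonic mouse ureters were analysed. Both arrays lay on 1 slide and were read in 1 scan, and each holds both conditions, so slide and scan are a single batch and every ratio was taken within it. By the labels, control RNA carried AlexaFluor647 (red) and NOGGIN RNA AlexaFluor555 (green) on array 1, and the reverse on array 2. Each array is 1 replicate.

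The deposited scanner files hold, per the file headers, spot intensity values that Agilent Feature Extraction (version 10.7.3.1, per the submitters' processing notes) measured from a custom design. The mean signals and local background medians are not normalized. The processed signals were background-subtracted and dye-normalized by the scanner software, per the file headers. The deposited log10 ratio column is red over green of the processed signals. The authors also deposited a table with a signed score per probe. Set against the scanner values it proved to be a signed linear fold change, with medians of 1 on both arrays and no value between -1 and 1. Its values correlated with red over green at 0.838 on array 1 and at -0.884 on array 2, so it is control over NOGGIN by the dye labels although the titles set NOGGIN against control. Which of the 2 is right stays unknown, and its normalization is not given in the sources used here.

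From the mean signals, background was corrected by normexp with an offset of 50 and each array was normalized by loess with control spots at weight 0 (limma 3.58.1, R 4.3.3). The design has 17214 negative control spots. Control spots and spots flagged as outliers (3.36% and 3.09% of spots) were left out, and no spot was saturated. The 4 spots of a probe were averaged. A probe was kept where most of its spots were well above background in at least 1 channel on both arrays. For each gene the brightest probe was used. Probe names were updated through RefSeq accessions without versions in a gene table of assembly GRCm38.p6, used for names only: 28328 probes (71.8%) matched, 1359 names changed, and the file's name was kept otherwise. Probe positions are those of the files (mm9); exon and UTR annotation of that build was not used here. Of the 488 genes past the 1.5-fold rule, 119 had several kept probes, and 0 of these had a probe 1.5-fold in the other direction. That count leaves out probes with little change, such as other kept probes of Irs4 (0.02) and Synpo2 (-0.12 and 0.01). It does not show that the probes of a gene gave the same size.

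Log2 ratios were fitted with limma's lmFit and eBayes with 1 coefficient, +1 where the channel labelled NOGGIN is red and -1 where it is green, which leaves 1 residual degree of freedom and gained 4.34 prior degrees of freedom. P-values are two-sided and adjusted by Benjamini-Hochberg over all features. The fold rule counted genes at least 1.5-fold in the same direction on both arrays. The 22 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, for lists with at least 5 measured genes; camera was repeated with an estimated correlation, and list medians were set among 10000 random lists matched on intensity. Bootstrap intervals resampled genes 10000 times. Figures were drawn with matplotlib 3.10.9.

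The design, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule takes the 8 highest and 8 lowest genes that pass the adjusted p and the 1.5-fold rule, filled with genes that pass only the 1.5-fold rule; the 3 members with the largest absolute log2 ratio of each primary list; up to 2 members of each other list that pass the adjusted p; and always Id1, Id2, Id3, Nog, Bmp4, Myocd, Acta2 and Upk3a. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen. Alternatives covered the background correction, normalization, filter, flagged spots, averaging, probe choice, variance model, thresholds, the authors' values and each array alone.

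The gene test was tested on simulated ratios for 22316 features with 200 changed. At a log2 change of 2, 94% of 100 genes passed an adjusted p of 0.05 and 100% passed the fold rule; at a log2 change of 1, 3% and 78% did; of the 22116 unchanged features, 0.05% and 0.8% did. In 50 simulated draws of a list of 15 genes, camera called 100% of lists shifted by 0.8 and 2% of unshifted lists at an unadjusted p of 0.05. The simulated noise was independent between genes, so these shares do not show how camera behaves on lists of correlated genes.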

Results

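Embryonic mouse ureters were compared after culture with and without NOGGIN, a secreted protein that binds bone morphogenetic proteins (BMPs) and keeps them from their receptors. Per the labels, ureters of NMRI wild-type embryos (E13.75, days after conception) were cultured for 18 h with 10 µg/ml NOGGIN or without it, and 200 ng of total RNA per sample was labelled. RNA was read on 2 two-colour arrays, each with 1 control and 1 NOGGIN sample, and the dyes were exchanged between the arrays. The comparison asks which transcripts differ when BMP signalling in the ureter is blocked. Of 39429 probes with 4 spots each, 29645 were kept, for 22316 genes or unnamed features. On array 1, 76.9% of probes were well above background in the channel labelled NOGGIN and 65.3% in the channel labelled control; on array 2 the shares were 66.4% and 76.4%, so the green dye gave more detected probes on both. The number of arrays limits the precision. The labels number the samples but do not say that the 2 pairs came from separate litters. P-values of the gene test measure only the spread between these samples, with a variance partly drawn from all genes. Those of camera with the preset correlation set the genes of a list against the other genes. They measure no spread between cultures.

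The direction of the comparison was not settled by the sources. By the dyes in the labels, BMP target genes were higher in the channel labelled NOGGIN: Id1, a transcription regulator induced by BMP-SMAD signalling, had a log2 ratio of 2.14 ± 0.09 (SD, n = 2). The authors' deposited table gives the Id1 probe signed fold changes of -4.65 and -4.53 on the 2 arrays, and its titles set NOGGIN against control, which read in that order is the opposite direction. Every signed value here follows the dye labels, as the channel labelled NOGGIN over the channel labelled control. If the dye labels are exchanged, every sign turns and the sizes stay.

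By the 1.5-fold rule, 210 genes were higher and 278 were lower in the channel labelled NOGGIN on both arrays, 488 in all, and 53 genes passed 1.5-fold in opposite directions on the 2 arrays. In the simulated ratios 0.8% of 22116 unchanged features passed this rule, so some of the 488 may be noise. The simulation added a dye effect to a variance that already held it, so it does not give their number. No gene passed an adjusted p of 0.05 in limma's moderated test. The lowest adjusted p was 0.0735, 36 genes were under 0.1, and 1347 genes (6.04%) had an unadjusted p under 0.05. The count past the adjusted threshold depended on the variance model and the filter: it was 141 with limma's trend and robust options and 97 among probes above background in both channels. Values of single genes below are therefore given as values. Across genes, which are not independent replicates, the log2 ratios of the 2 arrays had a Pearson correlation of 0.179 and a Spearman correlation of -0.069.

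**Figure D1:**
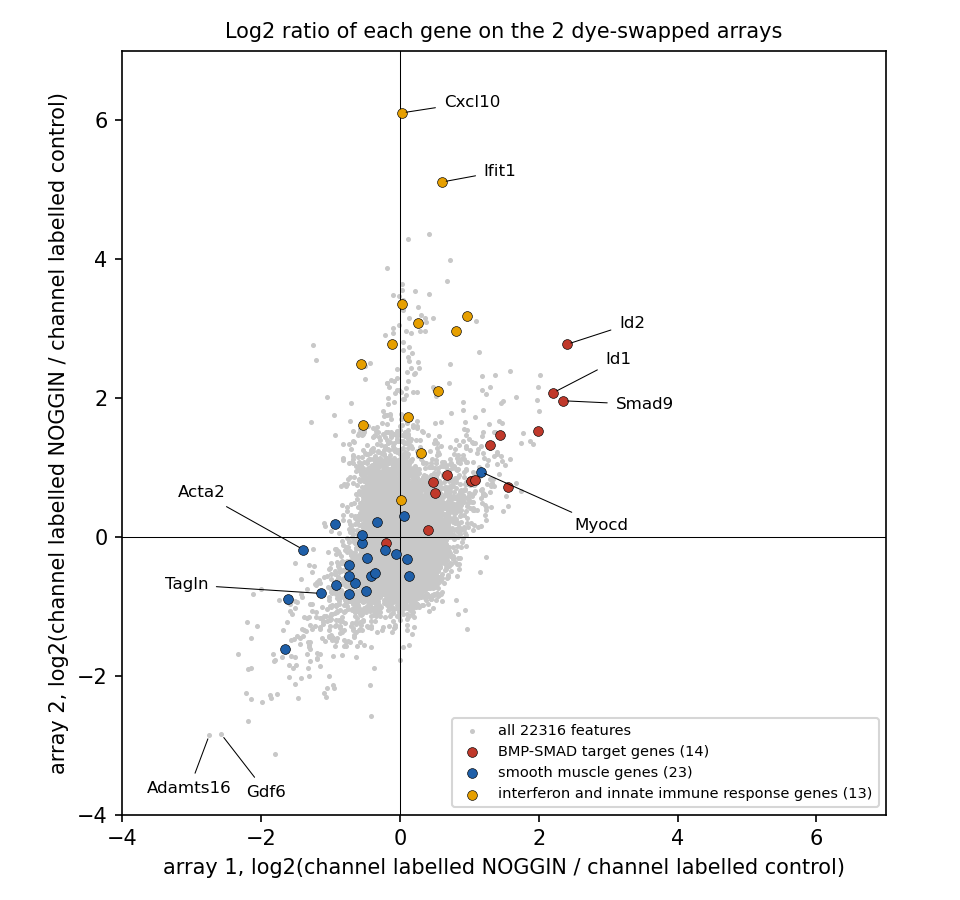
Log2 ratio of each of 22316 features on array 1 (x axis) and array 2 (y axis), channel labelled NOGGIN over channel labelled control, with 3 gene lists in colour and 1 point per gene. The BMP-SMAD targets lie along the diagonal (Id1 at 2.21 and 2.08), most smooth muscle genes lie below 0 on both arrays, and interferon genes such as Cxcl10 (0.03 and 6.11) are high on array 2.

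BMP-SMAD target genes stood together on the higher side. Of 14 measured members, 10 were at least 1.5-fold higher on both arrays, 0 were lower and 4 were neither. Besides Id1 (probe on chromosome 2, 152563083 to 152563142, mouse build mm9), the largest log2 ratios were 2.59 ± 0.26 (SD, n = 2) for Id2, another inhibitor of basic helix-loop-helix factors, and 2.16 ± 0.28 for Smad9, a receptor-regulated SMAD. Id3 had 1.45 ± 0.03. Adjusted over the list alone, 12 members passed 0.05 in limma's test, all of them higher, against 0 adjusted over all genes. The list shifted as a set by camera with a preset correlation (median 1.05, adjusted p = 8.14e-25), with medians of 1.19 on array 1 and 0.86 on array 2. With an estimated correlation its p was 0.0564 and its adjusted p = 0.691, and no list passed 0.05 with that estimate, which rests on 1 residual degree of freedom.

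BMP ligands, receptors and antagonists went both ways. Of 24 measured, 2 were higher and 5 were lower by the 1.5-fold rule, and the list did not pass by camera (adjusted p = 0.259). The ligand Bmp2 had a log2 ratio of -2.09 ± 0.33 (SD, n = 2), Bmp4 had -1.02 ± 0.12 and the antagonist Nbl1 had -1.25 ± 0.05, against the direction of the BMP targets. Nog, which encodes noggin itself, had 0.89 ± 0.10 and lay in the direction of the targets. Over the other settings it ran from 0.82 to 1.45. The added protein carries no transcript, so Nog does not check the labels. Adjusted over the list alone, 3 members were higher and 5 were lower.

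Smooth muscle genes were mostly on the lower side, opposite to the BMP targets. Of 23 measured, 1 was higher, 6 were lower and 16 were neither by the 1.5-fold rule, and adjusted over the list alone 1 was higher and 9 were lower, against 0 adjusted over all genes. The cardiac troponin gene Tnnt2 had a log2 ratio of -1.63 ± 0.03 (SD, n = 2), the actin-binding Synpo2 had -1.26 ± 0.51, and the smooth muscle actin gene Acta2 had -0.79 ± 0.86, with -1.39 on array 1 and -0.18 on array 2. Over the other settings Tnnt2 ran from -2.23 to -1.61, a range that its SD leaves out. The 3 kept probes of Synpo2 disagreed, since the 2 dimmer ones had -0.12 and 0.01. Myocd, the transcriptional coactivator that drives smooth muscle genes, was opposite in sign to most of the list, with 1.05 ± 0.16 (probe on chromosome 11, 64991930 to 64991989, mm9). The set shifted down by camera with the preset correlation (median -0.44, adjusted p = 2.84e-11), and its adjusted p = 0.691 with an estimated correlation.

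Fibroblast and matrix genes shifted down beside them (median -0.30, camera adjusted p = 1.88e-08), with 15 of 19 lower on both arrays but only 1 past 1.5-fold and 1 lower adjusted over the list alone. Their median was -0.193 on array 1 and -0.348 on array 2. Skeletal and cardiac muscle markers shifted down too (median -0.67, camera adjusted p = 1.38e-05): of 9 measured, 2 passed the 1.5-fold rule as lower, and adjusted over the list alone 1 was higher and 5 were lower. Nephron and renal progenitor markers shifted down (median -0.17, camera adjusted p = 0.00043), with 2 of 12 lower by the 1.5-fold rule and 2 adjusted over the list alone; on array 2 alone their median of -0.15 was at the 15.61th percentile of random lists. TGF-beta response genes passed narrowly (median -0.16, camera adjusted p = 0.0493), with 1 higher, 1 lower and 10 neither of 12; adjusted over the list alone 1 was higher and 4 were lower. The higher member, Smad7, is also in the list of BMP targets. Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.691), and the TGF-beta call was lost on ranks (adjusted p = 0.186), with no background correction (median -0.159), on processed signals (-0.143), with scale normalization (-0.154), over all probes (-0.149) and on the authors' deposited values (-0.175).

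Urothelial genes went both ways. Of 27 measured, 2 were higher, 3 were lower and 22 were neither by the 1.5-fold rule; the median was -0.001 with a 95% bootstrap interval over genes from -0.162 to 0.202, and camera gave an adjusted p of 0.947. Adjusted over the list alone, 2 were higher and 4 were lower. Pparg, a nuclear receptor of urothelial differentiation, had 1.64 ± 0.20 (SD, n = 2). Krt20, a keratin of superficial cells, had -1.27 ± 0.61, and the tight junction gene Cldn3 had -1.15 ± 0.03. Upk3a, a uroplakin, had 0.07 ± 0.25. The other uroplakins differed from it: Upk3b (0.89), Upk1a (0.83) and Upk2 (0.35) had means above 0 and Upk1b (-0.16) below 0.

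Among other signalling lists, the hedgehog and ureteric mesenchyme genes did not pass (camera adjusted p = 0.776): of 17, 2 were higher and 1 was lower by the 1.5-fold rule, and adjusted over the list alone 2 were higher and 1 was lower. Sox9 had 1.21 ± 0.01 (SD, n = 2), the ureteric mesenchyme factor Tbx18 had 0.77 ± 0.17 and the hedgehog co-receptor Cdon had -0.75 ± 0.18. The ureteric bud tip and RET-FGF response genes did not pass (median -0.131, adjusted p = 0.0606), with 1 of 14 past 1.5-fold and 0 adjusted over the list alone. They passed with no filter on dim probes (median -0.152), with spot medians (-0.124) and over all probes (-0.131), and the median was -0.238 on array 1 and -0.269 on array 2. Wnt11 had -0.82 ± 0.21 and Gdnf had -0.70 ± 0.20. The members went both ways: 6 were lower on both arrays and 3 were higher, namely Ret (0.25), Etv4 (0.25) and Cxcr4 (0.34). WNT-beta-catenin response genes passed by camera as higher (median 0.05, mean 0.23, adjusted p = 0.0284) but not with an estimated correlation (adjusted p = 0.691) or on ranks (adjusted p = 0.498), and not on processed signals (median 0.008), over all probes (0.018) or on the authors' deposited values (0.031). The median was 0.118 on array 1 and 0.157 on array 2. That shift rested on 3 of 16 genes, which also passed adjusted over the list alone: Wif1 (1.51 ± 0.45) and Dkk2 (0.84 ± 0.18), which encode secreted WNT inhibitors, and the transcription factor Sp5 (1.28 ± 0.34). Retinoic acid pathway genes did not pass by camera (median -0.221, adjusted p = 0.259), although the median was at the 0.01th percentile of random lists; it was 0.016 on array 1 and -0.267 on array 2. Of 12, 1 was higher and 1 was lower both by the 1.5-fold rule and adjusted over the list alone. Tgm2 had -0.95 ± 0.20, Cyp26a1, a retinoic acid degrading enzyme, had 0.84 ± 0.13 and Aldh1a3 had 0.62 ± 0.57.

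Interferon and innate immune response genes passed by camera as higher (median 1.34, adjusted p = 1.37e-10), but the shift was carried by array 2, with medians of 0.12 on array 1 and 2.78 on array 2. On array 1 alone the median was at the 87.57th percentile of random lists matched on intensity. By the 1.5-fold rule 3 of 13 were higher on both arrays, none passed adjusted over the list alone, and with an estimated correlation the adjusted p = 0.691. Ifit1, an interferon-induced gene, had 0.61 on array 1 and 5.11 on array 2. Macrophage markers went both ways on array 2, with a median of -0.19; Adgre1 (1.27) and Lyz2 (1.23) were higher there and Cx3cr1 (-1.27) and Mrc1 (-0.63) were lower.

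The genes named here had the largest log2 ratios among those past the 1.5-fold rule on both arrays, and none passed the adjusted threshold. Cxcl10 (3.07), Ifi44 (2.39) and Ifi47 (2.20) had means in that range but were below 1.5-fold on array 1. Of the named genes on the higher side, 4 were interferon-induced and uneven: Ifit1 (2.86 ± 3.19, SD, n = 2), Ifit3b (2.36 ± 2.30), Oasl2 (2.18 ± 2.12) and Rtp4 (2.11 ± 1.43). Ifit3b was above background in the channel labelled control on 1 array, and it has near copies that its probe may also read. The others were Id2, Smad9, Id1 and the protease gene Ctse (2.18 ± 0.22). On the lower side were Adamts16, a secreted protease (-2.80 ± 0.08; probe on chromosome 13, 70867148 to 70867207, mm9), Gdf6, a BMP family ligand (-2.71 ± 0.19), the embryonic myosin Myh3 (-2.46 ± 0.94), the growth factor Fgf18 (-2.42 ± 0.33), Prmt8 (-2.24 ± 0.14), Irs4 (-2.23 ± 0.03), the cadherin Cdh3 (-2.18 ± 0.27) and Bmp2. Prmt8 and Irs4 were above background in the channel labelled NOGGIN on 1 array only, so their size and place in the order are uncertain and their SDs leave that out; over the other settings Prmt8 ran from -3.45 to -2.15 and Irs4 from -2.89 to 0.02. The other kept probe of Irs4 had 0.02, that of Adamts16 had -1.42 and that of Myh3 had -1.75.

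**Figure D2:**
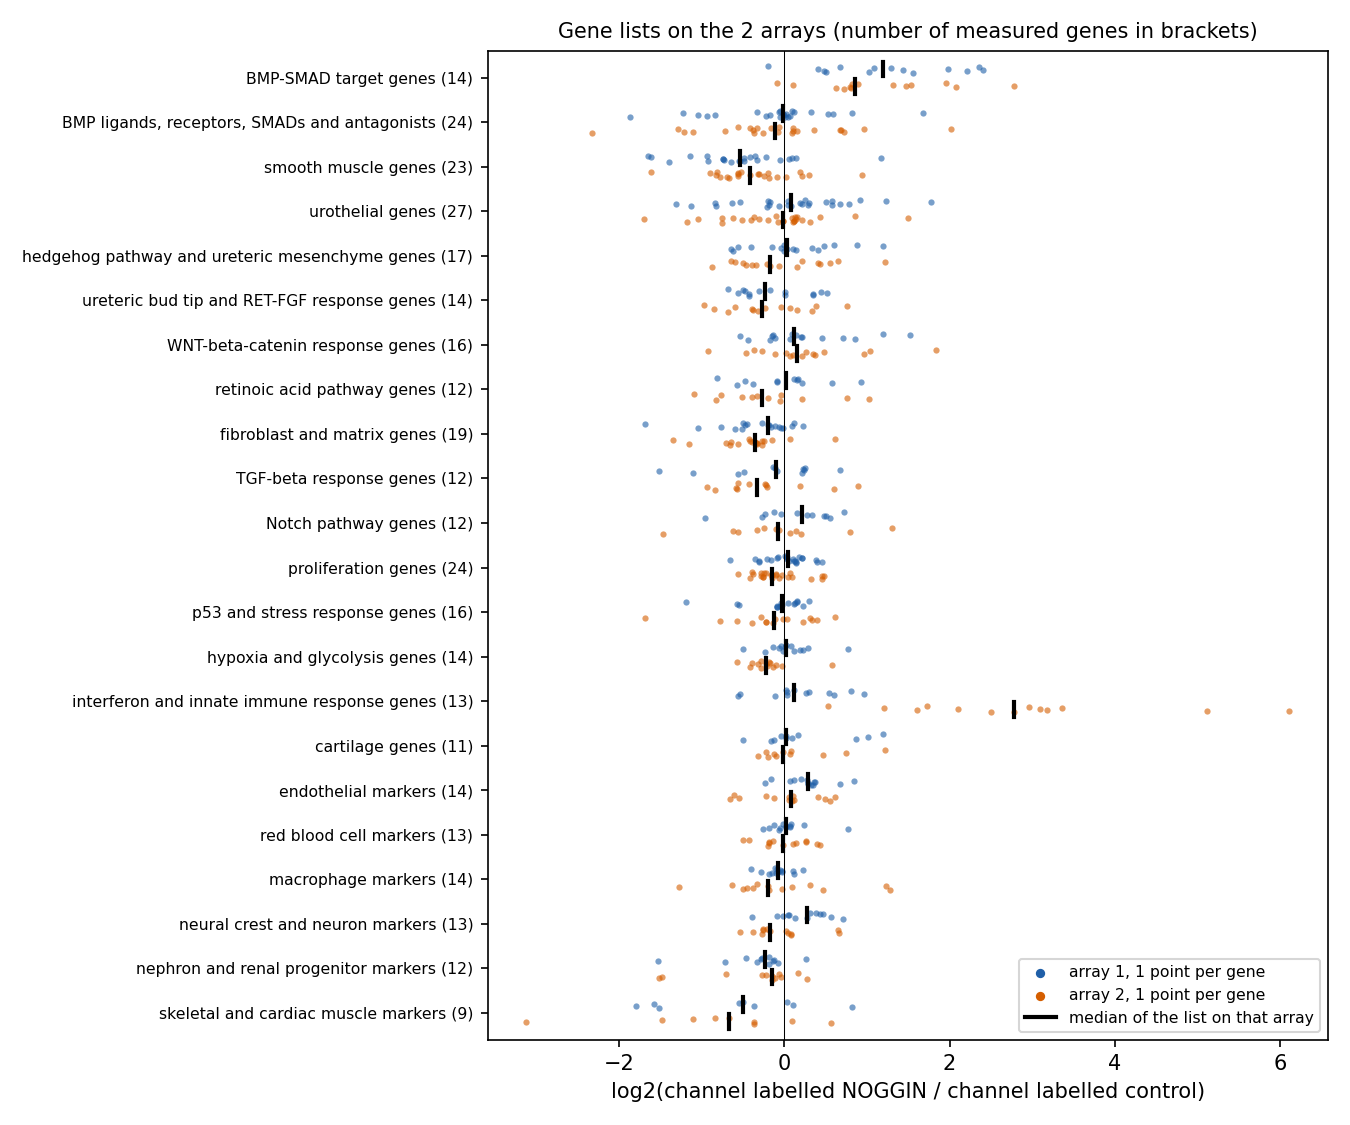
Log2 ratio (x axis) of each measured gene in 22 lists (rows), channel labelled NOGGIN over channel labelled control, with array 1 and array 2 as separate points and black bars at each list's median per array. The BMP-SMAD targets have medians of 1.19 and 0.86, the smooth muscle genes -0.54 and -0.41, and the interferon genes 0.12 and 2.78.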

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

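The separate-channel fit without a dye term and the percentiles on single arrays were chosen after the data were seen. The planned separate-channel fit with a dye covariate was not run, since 2 arrays leave it no residual degree of freedom within spots. A single array gives no limma or camera test and no correlation between arrays; its list percentiles describe that array and are no test. Signal over background limits dim probes such as those of Irs4.

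The number of genes past an adjusted p of 0.05, 0 as reported (1347 at an unadjusted p under 0.05), became 35 with no background correction, 114 with median centring, 97 when both channels had to be above background, 22 with outlier spots kept, 141 with trend and robust variance, and 36 at an adjusted p of 0.1. It stayed 0 in the other 8 settings. The fold-rule count of 488 became 853 on processed signals and 149 at 2-fold, and from 961 to 2631 on single arrays. With median centring, which leaves the dye trend in, 895 genes passed in opposite directions against 152 higher and 195 lower; on processed signals it was 435. The 9 lists shifted became 0 with an estimated correlation and were within 1.5 times of 9 in the other 11 settings. The correlation of the arrays across genes, 0.179, became 0.218 on processed signals, -0.167 with median centring, 0.164 with both channels above background, 0.157 with spot medians and 0.295 on the authors' values. The causes were not tested.

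Apart from the estimated correlation, BMP-SMAD targets and smooth muscle genes kept their direction in all 15 settings and their call in each tested one, the smooth muscle medians running from -0.54 to -0.41 on single arrays. The urothelial median, near 0, turned sign with no background correction (0.001), on processed signals (0.039), with scale normalization (0.014), with flagged spots kept (0.037), over all probes (0.023) and on the authors' values (0.039), and ran from -0.019 to 0.077 on single arrays. The hedgehog median, -0.053 as reported, turned to 0.002 with scale normalization and ran from -0.169 to 0.028 on single arrays. Bud tip genes passed by camera with no dim-probe filter (-0.152), spot medians (-0.124) and all probes (-0.131), lay at the 2.18th percentile of random lists and the 0.07th on array 1, and ran from -0.269 to -0.238 on single arrays. The WNT call was lost on processed signals (0.008), over all probes (0.018) and on the authors' values (0.031), at the 90.03rd percentile and the 92.56th on array 1, with 0.118 to 0.157 on single arrays. Retinoic acid genes lay at the 0.01st percentile and the 1.19th on array 2, and ran from -0.267 to 0.016 on single arrays. Cartilage genes turned to -0.036 with median centring, -0.029 with flagged spots kept and -0.004 with spot medians, and red blood cell markers to -0.058 with no filter and -0.022 with flagged spots kept. Of 572 values of the 41 named genes under alternatives, 2 turned sign: Irs4 (0.015) when both channels had to be above background, because its other probe was then used, and Upk3a, near 0, on array 2 alone (-0.102); 81 passed the adjusted threshold where the reported value did not.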

Other observations

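Tests on the BMP targets and on the interferon genes were chosen after those results were seen; those on smooth muscle and on the fold-rule counts were written before.

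Endothelial markers passed by camera as higher (median 0.20, adjusted p = 0.0284, and 0.691 with an estimated correlation), with 0 of 14 past 1.5-fold. The call was lost with median centring (median 0.166). The median was 0.286 on array 1 and 0.081 on array 2, where they lay at the 90.72th percentile of random lists. Proliferation genes (0 of 24 past 1.5-fold, adjusted p = 0.66), hypoxia and glycolysis genes (0 of 14, 0.259), p53 and stress genes (1 of 16, 0.29), Notch genes (2 of 12, 1 in each direction, 0.737), neural crest and neuron markers (0 of 13, 0.259), red blood cell markers (0 of 13, 0.776), macrophage markers (0 of 14, 0.269) and cartilage genes (2 of 11, 0.164) did not pass by camera. Neural crest and neuron markers had medians of opposite sign on the arrays (0.272 on array 1, at the 99.87th percentile of random lists, and -0.172 on array 2), as did Notch genes (0.217 on array 1, at the 99.04th percentile, and -0.078 on array 2). The members of these lists past 1.5-fold on both arrays were the cell death gene Pmaip1 (-1.19 and -1.68) and the Notch ligand Dll1 (-0.96 and -1.46) as lower, and the Notch regulator Nrarp (0.72 and 1.30), the cartilage matrix gene Hapln1 (1.02 and 0.75) and Sox9 (1.20 and 1.21) as higher. In lists that camera called lower, the muscle regulator Myog had -1.57 and -1.48, the progenitor factor Meox1 had -1.53 and -1.48 and the matrix gene Ogn had -1.68 and -1.34.

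Genes past 1.5-fold in opposite directions on the arrays numbered 10.9% of those in the same direction. That is under the fifth set beforehand as arguing against dye bias and noise alone, which were set to give at least as many opposite genes. That holds on the loess values. On processed signals the counts were 435 opposite against 853, between these bounds and undecided. With median centring the opposite count exceeded the other, as set for dye bias and noise.

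NOGGIN blocks BMP ligands, yet BMP targets were higher in the channel labelled NOGGIN. Dye bias is argued against by the dye swap: the median was 0.858 on array 2, on the same side as on array 1. Dye labels exchanged on both arrays are a candidate explanation, since 100% of the deposited values of genes past the 1.5-fold rule have the opposite sign when read in title order. Such a share follows from the orientation of the deposited table on each array, so the number of genes adds no weight. Reading the signs this way assumes the order of the titles. The deposited values come from the same arrays, so only the orientation given to each array bears on which channel held NOGGIN. That orientation conflicts with the dye labels, and what was pipetted is not recorded beyond these. The ratios alone cannot tell a true rise of BMP target transcripts under NOGGIN from exchanged labels. Exchanging the labels turns the sign and keeps the size by construction, so the median of 1.046 has no bearing on it. With exchanged labels the targets would be lower with NOGGIN, which is the direction of a block of BMP ligands.

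Smooth muscle genes moved opposite to the BMP targets, whichever sign is right. A different share of mesenchymal and epithelial tissue would move fibroblast and matrix genes with them and urothelial genes away from them. The first part was near the 0.3 set beforehand over both arrays, with a fibroblast and matrix median of -0.298 and 15 of 19 genes lower on both. By array it was uneven, at -0.193 on array 1 and -0.348 on array 2. The second was not met: the urothelial median was -0.001, with an upper bound of 0.202, below the 0.3 set for it. An effect of the treatment and a lower TGF-beta response stay open, the median of the TGF-beta genes being -0.159, between the bounds set, with -0.10 on array 1 and -0.33 on array 2. These are not the only possible causes. Skeletal and cardiac muscle markers were lower too (median -0.67, with 6 lower and 2 higher on both arrays), and a different share of such tissue was not tested.

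The interferon response may belong to 1 culture of array 2. Of the 100 genes that differed most between the arrays, 97 were higher on array 2, with Cxcl10 (0.03 and 6.11) first. Some of them turned sign with the dyes, such as Kcnab1 (-1.28 and 1.66) and Ccl7 (-1.21 and 2.54), while Ifit3 (0.97 and 3.18) did not. A dye effect can also make a gene higher on array 2, so this count does not exclude dye bias. For the interferon list, dye bias would have turned the sign on array 1, where the list median was 0.118. Of its 13 genes, 10 were higher on both arrays, while Ccl2 (-0.56), Il6 (-0.53) and Cxcl1 (-0.11) were below 0 on array 1. More macrophages in that sample are argued against by their markers (median -0.194 on array 2), although Lyz2 (1.23) and Adgre1 (1.27) were higher there; Cx3cr1 (-1.27) and Mrc1 (-0.63) were lower. A treatment effect of the same size in both cultures is argued against by array 1, where the upper bound of the median was 0.546. That bound comes from resampling the list's genes on array 1, and it measures no spread between cultures. A response of unequal size to the treatment and a chance event in 1 culture stay open, and which culture it was depends on the dye labels.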
